A study of Homo sapiens with 6 samples.

How the data were processed

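Peak regions of DHX9 FLASH libraries from HEK293 cells were analysed. Per the labels' protocols, cells were irradiated with ultraviolet light, lysed and sonicated, and the protein was captured on beads carrying the antibody. RNA was trimmed with RNase I, its 3′ ends were repaired, and barcoded adapters with random bases were ligated. Per the labels, the random bases served to merge PCR duplicates, 1 barcode told the antibodies apart and another told the replicates apart, and control and DHX9 material were mixed before the cDNA was made. Sequencing was paired-end. The submitters' processing notes name Bowtie2 2.2.6 and the assembly hg19. Per the files' second column, peaks were called with PEAKachu. Its version, control, threshold and settings, and the way in which the replicates were combined, are not given in the sources used here. Because reads from repeats can map to many places, the treatment of such reads could change which peaks were called, and it is not given either.

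The deposited values are the first and last base of each peak region and its strand, counted from 1. The authors' score column was empty in every line (0 cells with a number in either list). Each list was tied to its antibody by the labels of both of its replicates, so 2 replicates stand behind each list and cannot be separated. No column of unknown origin was present. Neither list held a duplicated region, and the peak numbers in the identifiers ran without a gap on all 25 sequences. On 11 of the 24 sequences shared with the GRCh38 annotation, peaks lay beyond its last gene, so that annotation was not used with these positions and no position was converted between assemblies. No read depth could be given. Intervals on shares are 95% Wilson intervals, or percentile intervals from 1000 resamplings of whole 100 kb windows, and they cover counting error only.

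A peak was called shared when it overlapped a peak of the other list by at least 1 nt on the same strand. Overlap was compared with 1000 random placements of the DHX9-Rb peaks, each within 50 kb on either side of its start and within the range of observed positions. The planned placement within annotated genes would need an annotation of hg19, and the window placement named beforehand as its replacement was used. Widths were compared with two-sided permutation tests on the difference of medians (100000 permutations). Peak numbers per chromosome, and per window of 100 kb holding at least 10 peaks in both lists together, were compared with two-sided Fisher's exact tests with Benjamini-Hochberg adjustment at 0.05. A peak was placed in a window by its midpoint. Peaks within a transcript are not independent, so these p-values describe the 2 lists, not new experiments. The comparisons of widths, chromosomes, windows and strands were chosen after the files had been seen. The overlap comparison and the rule for naming regions, the 10 windows of 100 kb with the most shared peaks, were fixed before the data were examined.

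Planned results on annotation classes, Alu content and orientation, inverted Alu partners, peaks per gene and the 11 fixed gene lists were not run, since they need the hg19 sequence or gene annotation. The planned use of a fold or score per peak was not possible because the lists hold none. One of the windows that differed between the antibodies, on chromosome X, counts in all tests and totals, but its position and peak numbers are not reported here. Alternatives covered the overlap rule, merging of peaks within 50 nt, the placement window, the sequences included, the window size and the minimum number of peaks.

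The overlap test was tested on simulated data with 6831 peaks. With peaks spread smoothly over 2000 kb, it returned -0.256% for lists sharing nothing beyond chance, 10.0% where 9.79% was planted and 29.5% where 29.6% was planted. With lists clustered within 100 kb, it returned 1.4% where nothing was planted (n = 6831 peaks, p = 0.01), so clustering at that scale alone adds to the excess. The lists themselves are crowded at shorter scales, as placement within 10 and 2 kb windows shows (32.2% and 51.0% of DHX9-mAb peaks overlapped by placed peaks). The window test recovered 16 of 20 windows planted with a 3-fold change among 853 windows and called 0 others. In that simulation the smaller list was the DHX9-Rb list thinned at random, with each peak kept or dropped on its own. Planted windows held at least 20 DHX9-Rb peaks, and all were raised in the smaller list. Recovery in sparser windows or in the other direction, and false calls where peaks come and go in groups, were therefore not measured. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.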

Results

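RNA sites of DHX9 were mapped in HEK293 cells, an established human line derived from embryonic kidney. DHX9, also called RNA helicase A, is a nuclear helicase that unwinds double-stranded RNA. The assay was FLASH, a form of cross-linking and immunoprecipitation in which ultraviolet light ties proteins to the RNA they touch. The protein was then pulled down with an antibody, and the attached RNA fragments were sequenced. The study used 2 antibodies against DHX9, labelled DHX9-mAb and DHX9-Rb, and a control immunoglobulin labelled IgG-Rb, each with 2 biological replicates. The values analysed here are 2 lists of peak regions, 1 for each DHX9 antibody and each standing for both of its replicates. They hold positions and strands in the human assembly hg19, with no height, fold or p-value per peak. The read depth behind each peak is therefore unknown. No values of the separate replicates and none of the IgG-Rb samples were used here. No replicate error or background level can stand beside a peak number, and the comparison of the 2 antibodies is the only check on a site. That comparison does not rest on fully separate libraries, because material was mixed before the cDNA was made. Regions are named by position, because the gene annotation at hand is on another assembly.

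The DHX9-Rb antibody gave many more peaks than the DHX9-mAb antibody, of nearly the same size and strand balance. DHX9-Rb had 21618 peaks and DHX9-mAb had 6831, a ratio of 3.16. The DHX9-Rb peaks covered 4859154 nt on their strands and the DHX9-mAb peaks 1450054 nt, a ratio of 3.35. The median peak was 201 nt wide with DHX9-Rb (interquartile range 152 to 273) and 191 nt with DHX9-mAb (146 to 256.5). The plus strand held 52.3% of the DHX9-Rb peaks and 52.2% of the DHX9-mAb peaks.

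The chromosomes richest in peaks were the same for both antibodies, and both lists reached all 25 sequences with a peak. Chromosomes 1, 17 and 19 together held 37.4% of the DHX9-Rb peaks and 38.6% of the DHX9-mAb peaks. Chromosome 19 had 2905 DHX9-Rb peaks, or 49.4 per Mb between the first and the last peak, against a median of 5.75 per Mb over chromosomes 1 to 22 and X. It had 1011 DHX9-mAb peaks, 17.2 per Mb against a median of 1.61. Chromosome 22 came next, with 34.9 DHX9-Rb and 12.2 DHX9-mAb peaks per Mb. Chromosome 17 followed with 27.9 and 7.73 per Mb. Chromosome 13 lay at the other end, with 107 DHX9-Rb peaks (1.14 per Mb) and 25 DHX9-mAb peaks (0.266 per Mb). Chromosome 18 had 113 and 31 peaks. The mitochondrial chromosome held 54 DHX9-Rb peaks and 50 DHX9-mAb peaks.

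The shares per chromosome differed little between the antibodies, except on the mitochondrial chromosome. Its share was 0.732% of the DHX9-mAb list (95% Wilson interval 0.556 to 0.964) and 0.25% of the DHX9-Rb list (0.192 to 0.326). Fisher's exact test, two-sided and adjusted by Benjamini-Hochberg over 25 sequences, passed 0.05 for 4 of them. By this exact test these were the mitochondrial chromosome (odds ratio 2.94, adjusted p = 2.46e-06), chromosome 7 (0.764, adjusted p = 0.0046), chromosome 17 (0.866, adjusted p = 0.0208) and chromosome 19 (1.12, adjusted p = 0.0299). Odds ratios above 1 mean a larger share of the DHX9-mAb list. Peaks lie in groups, so the test counts too many independent sites. When whole 100 kb windows were resampled, the 95% interval of the odds ratio, among these 4, excluded 1 for chromosomes 7 (0.638 to 0.883) and 17 (0.773 to 0.967). It included 1 for chromosome 19 (0.988 to 1.26). Without adjustment the intervals also excluded 1 for chromosomes 2 (0.691 to 0.975) and 14 (0.649 to 0.97), which had not passed the exact test. That of chromosome 1 (1.0 to 1.21) excluded 1 only before rounding, and chromosome 1 had not passed the exact test either. With peaks within 50 nt merged, chromosomes 17 and 19 no longer passed (Fisher's exact test, adjusted p = 0.085 for both). The mitochondrial chromosome lies in 1 window and could not be resampled.

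**Figure D1:**
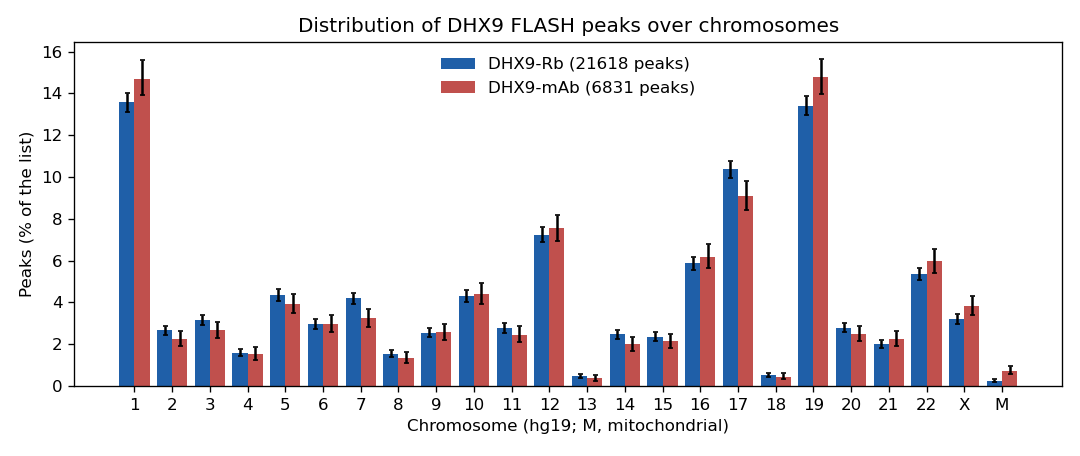
Share of each peak list on chromosomes 1 to 22, X and M of hg19, in percent of the list; blue bars are DHX9-Rb, red bars are DHX9-mAb, and error bars are 95% Wilson intervals, which cover counting error only. Chromosomes 1, 17 and 19 carry the tallest bars in both lists, and chromosomes 13, 18 and M the shortest.

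The 2 antibodies were compared site by site to see whether they recovered the same RNA positions. Of the 6831 DHX9-mAb peaks, 6011 overlapped a DHX9-Rb peak by at least 1 nt on the same strand. That is 88.0% (95% Wilson interval 87.2 to 88.8; 87.1 to 88.9 when 100 kb windows were resampled). Of the 21618 DHX9-Rb peaks, 6175 overlapped a DHX9-mAb peak, or 28.6% (Wilson 28.0 to 29.2). In nucleotides, 1070162 were covered by both antibodies, which is 73.8% of the DHX9-mAb sequence and 20.4% of the sequence covered by either. The DHX9-mAb list was thus nested for the most part within the DHX9-Rb list.

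This overlap exceeded that of peaks moved at random. In each of 1000 placements, every DHX9-Rb peak kept its width and strand and moved to a random place within a 100 kb window around it. The moved peaks overlapped 10.2% of the DHX9-mAb peaks on average, or 698.9 of them, with a highest count of 794. The observed number was 8.6 times that mean (one-sided randomization test over n = 6831 peaks, p = 0.001, the smallest that 1000 placements can give). Placement within narrower windows keeps more of the local crowding of peaks. Within 10 kb windows the placed peaks overlapped 32.2% of the DHX9-mAb peaks and the excess was 2.74-fold. Within 2 kb windows they overlapped 51.0% and the excess was 1.73-fold (randomization test over n = 6831 peaks, p = 0.001 for both).

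The agreement in position was close to the width of a peak. Shifting all DHX9-Rb peaks together by 50 nt left 87.8% of the DHX9-mAb peaks overlapped, and by 100 nt 84.6%. A shift of 200 nt, near the median peak width, left 66.3%, 300 nt left 57.6% and 500 nt left 55.6%. The overlap was still 48.7% at 1000 nt and 18.5% at 5000 nt, and fell to 2.85% at 50000 nt.

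**Figure D2:**
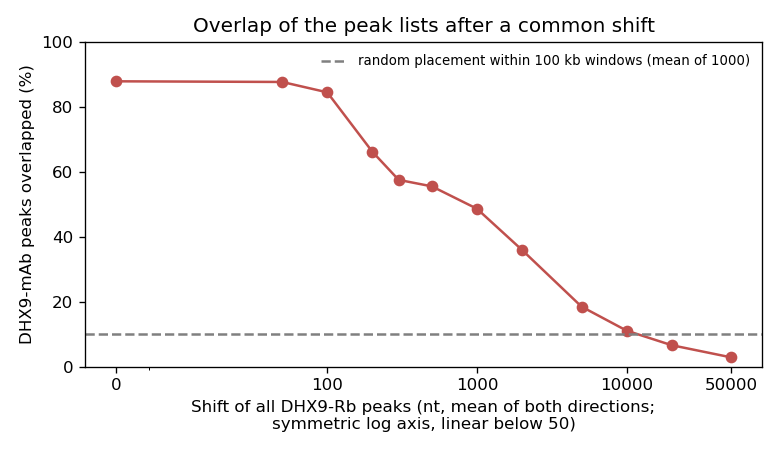
Percent of DHX9-mAb peaks overlapped by a DHX9-Rb peak on the same strand (vertical axis) after all DHX9-Rb peaks were moved by a common number of nucleotides (horizontal axis, symmetric log scale); points are means of both directions, and the dashed line is the mean of 1000 random placements within 100 kb windows. The curve starts at 88.0% and drops to 66.3% at 200 nt and to 18.5% at 5000 nt.

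Peaks found by both antibodies were wider than peaks found by one. In the DHX9-Rb list the median width was 243 nt for shared peaks and 190 nt for the other 15443 peaks. In the DHX9-mAb list it was 196 nt for shared peaks and 164 nt for the other 820. Both differences, 53 nt and 32 nt, exceeded those of 100000 permutations (two-sided permutation test, p = 1e-05 for each list, the smallest they can give). A wider region has more room to overlap another, so width and overlap are not independent measures.

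Peaks lay in dense groups along a strand, and the DHX9-mAb peaks lay for the most part in windows that DHX9-Rb also marked. In 100 kb windows, DHX9-Rb had peaks in 3430 windows and DHX9-mAb in 1936, and 1846 windows had peaks of both. Thus 95.4% of the DHX9-mAb windows also held a DHX9-Rb peak, and 53.8% of the DHX9-Rb windows also held a DHX9-mAb peak. Across the 3520 windows with a peak of either antibody, Spearman's rho between the peak numbers was 0.69. Windows are not replicates, so no p-value is attached. The 646 windows with at least 10 DHX9-Rb peaks held 63.7% of that list, and in 464 of them (71.8%) all DHX9-Rb peaks lay on 1 strand. Neighbouring DHX9-Rb peaks less than 1 kb apart were on the same strand in 99.5% of 12991 cases. For neighbours over 100 kb apart this share was 52.7%.

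The 10 windows with the most shared peaks held 420 of the 6175 shared DHX9-Rb peaks, or 6.8%. The densest was on chromosome 1, between 113503630 and 113584363, with 127 DHX9-Rb and 57 DHX9-mAb peaks, all on the plus strand. On chromosome 16, between 89800955 and 89881723, 90 DHX9-Rb and 54 DHX9-mAb peaks lay on the minus strand. Another window of chromosome 1, from 21406014 to 21500030, held 110 and 49 peaks, all on the minus strand. On chromosome 19, from 39404739 to 39466183, the antibodies gave almost equal numbers, 53 DHX9-Rb and 55 DHX9-mAb peaks on the minus strand. A plus-strand window of the same chromosome, from 58300715 to 58385035, held 74 and 39. One more window of chromosome 19, from 40805981 to 40871778, had peaks on both strands, with 35 plus and 47 minus DHX9-Rb peaks and 17 and 17 DHX9-mAb peaks. On chromosome 17, from 1244385 to 1300046, there were 81 and 37 minus-strand peaks. The other members were the mitochondrial chromosome and a pair of windows on chromosome 1. One of these, from 151123007 to 151199876, held 75 DHX9-Rb and 35 DHX9-mAb peaks, and the other, from 16145613 to 16199311, held 84 and 35.

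**Figure D3:**
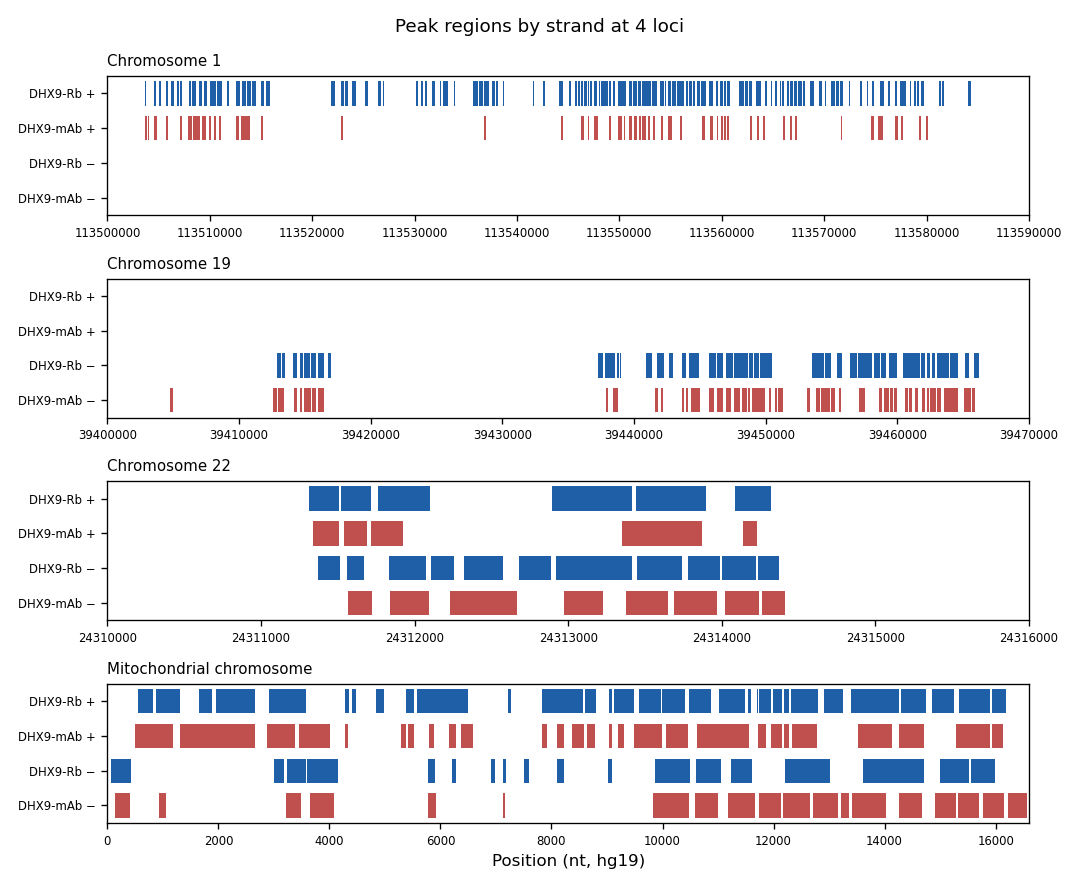
Peak regions drawn to scale at 4 loci of hg19, with position in nucleotides on the horizontal axis and 1 row per antibody and strand; blue boxes are DHX9-Rb peaks and red boxes are DHX9-mAb peaks. The loci on chromosomes 1 and 19 have peaks on 1 strand only, and those on chromosome 22 and the mitochondrial chromosome on both.

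The share of DHX9-Rb peaks that DHX9-mAb also marked was higher where DHX9-Rb peaks were dense. It was 16.1% (Wilson 14.1 to 18.3) in the 1150 windows with 1 DHX9-Rb peak. It was 23.1% (21.8 to 24.5) in windows with 5 to 9 peaks and 40.1% (38.0 to 42.2) in the 33 windows with 50 or more. A DHX9-mAb peak was present in 19.8% of the windows with 1 DHX9-Rb peak and in 100% of those with 20 or more. The DHX9-Rb peaks of dense windows were also wider, with a median of 230 nt in the windows with 50 or more and 163 nt in those with 1. Overlap under random placement was not computed for each density class, and crowding alone can raise it. The rise therefore does not show closer agreement of sites in dense windows.

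**Figure D4:**
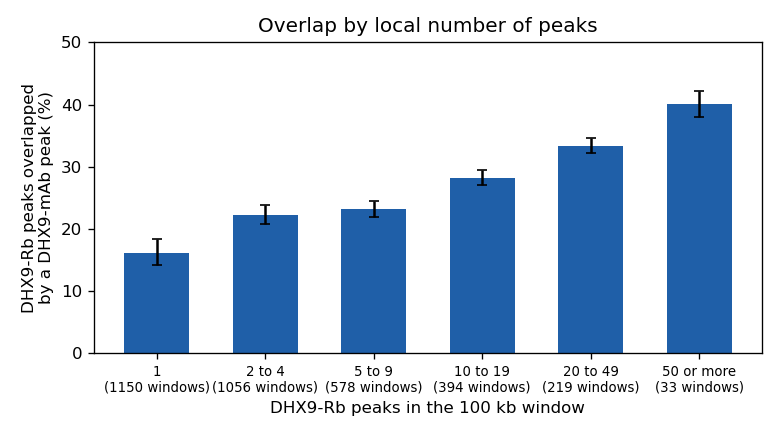
Percent of DHX9-Rb peaks overlapped by a DHX9-mAb peak (vertical axis) in 100 kb windows grouped by their number of DHX9-Rb peaks (horizontal axis, with the number of windows); error bars are 95% Wilson intervals. The bars go from 16.1% in windows with 1 peak to 40.1% in windows with 50 or more.

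A few regions took a larger part of one list than of the other. Fisher's exact test on the peak numbers of the 818 windows with at least 10 peaks, adjusted by Benjamini-Hochberg, passed 0.05 in 6 windows. All 6 had the larger part in the DHX9-mAb list. Of these, 5 are described here. The window of chromosome 19 from 39404739 to 39466183 had an odds ratio of 3.3 (Fisher's exact test, adjusted p = 1.44e-06). A pair of windows on chromosome 1 followed. The first ran from 204504456 to 204527048, with 19 DHX9-mAb and 14 DHX9-Rb peaks (odds ratio 4.3, exact test, adjusted p = 0.0061). The second ran from 23618464 to 23664030, with 25 and 21 peaks (odds ratio 3.78, exact test, adjusted p = 0.00254). The others were the mitochondrial chromosome and the window of chromosome 16 from 89800955 to 89881723 (odds ratio 1.91, exact test, adjusted p = 0.0373). Without adjustment, 54 windows passed 0.05, of which 45 had the larger part in the DHX9-mAb list and 9 in the DHX9-Rb list. Among 818 tests, chance alone can add many such unadjusted calls. In windows of 200 kb, 1 had the larger part in the DHX9-Rb list after adjustment. In windows of 100 kb none had, but most could not have. Even with peaks of DHX9-Rb alone, a window needed 32 peaks to reach the largest p that passed. Only 188 of the 818 windows had that many in both lists together. With DHX9-mAb alone 6 peaks were enough, so the common direction of the 6 windows says little about the other direction. The window with the most DHX9-Rb peaks and no DHX9-mAb peak was on chromosome 17 from 73116863 to 73176092, with 19 peaks (Fisher's exact test, unadjusted p = 0.012, adjusted p = 0.46). Next came adjoining windows on chromosome 3. The first held 17 peaks from 49010024 to 49099787 and the second 15 from 49100820 to 49124544 (Fisher's exact test, adjusted p = 0.512 and 0.634). Their border at 49100000 lay between these peaks, so the 100 kb windows tested them apart. Windows with DHX9-mAb peaks and no DHX9-Rb peak were rare. The largest, on chromosome 5 from 14847903 to 14866303, held 2 DHX9-mAb peaks. These windows without a partner were chosen after the lists had been seen.

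The mitochondrial chromosome was covered on both strands by both antibodies. DHX9-mAb had 31 peaks on the plus strand, covering 9115 nt, and 19 on the minus strand, covering 6833 nt. DHX9-Rb had 35 and 19 peaks, covering 10682 nt and 6333 nt. Of the 50 DHX9-mAb peaks 46 overlapped a DHX9-Rb peak, and of the 54 DHX9-Rb peaks 43 (79.6%) overlapped a DHX9-mAb peak. Coverage was uneven on both strands. On the minus strand DHX9-mAb covered 15.5% of positions 1 to 8282 and 67.0% of positions 8283 to 16565, and DHX9-Rb covered 23.6% and 52.9%. On the plus strand the shares were 48.1% and 62.0% with DHX9-mAb and 50.3% and 78.7% with DHX9-Rb. Mitochondrial peaks had a median width of 334.5 nt with DHX9-mAb and 347 nt with DHX9-Rb, against 191 nt and 201 nt elsewhere.

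Peaks facing each other on opposite strands were common on the mitochondrial chromosome and rare elsewhere. There, 62.0% of DHX9-mAb peaks (Wilson 48.2 to 74.1) and 59.3% of DHX9-Rb peaks (46.0 to 71.3) overlapped a peak of the other strand in the same list. In the rest of the genome 13 of 6781 DHX9-mAb peaks (0.192%) and 112 of 21564 DHX9-Rb peaks (0.519%) did so. The difference passed Fisher's exact test in both lists (two-sided p = 1.81e-61 and 3.88e-57). Random placement of the mitochondrial peaks gave 59.1% and 59.0%, so these shares did not exceed what the coverage of the strands gives (one-sided randomization test over n = 50 and n = 54 peaks, p = 0.434 and 0.543). Outside the mitochondrial chromosome, random placement within 100 kb windows gave 18.3 DHX9-mAb and 170 DHX9-Rb peaks on average. The DHX9-Rb number lay below this (one-sided randomization test, n = 21564 peaks, p = 0.001), and the DHX9-mAb number did not fall below it beyond chance (n = 6781 peaks, p = 0.115). Placement moved each peak on its own and so broke up groups on 1 strand. DHX9-Rb neighbours less than 1 kb apart were on the same strand in 99.5% of cases. A number below placement can follow from this grouping alone, so it does not show that facing peaks are avoided. The facing peaks were concentrated at few places. With DHX9-Rb, 31 of the 112 lay on chromosome 1 between 16165088 and 16173446, 14 on chromosome 22 between 24311316 and 24314374, and 12 on chromosome 19 between 3539680 and 3543400. All 13 facing DHX9-mAb peaks lay at the first 2 of these places, 4 on chromosome 1 and 9 on chromosome 22.

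One unplaced contig of the assembly carried a single peak in each list. On the contig named chrUn_gl000220, DHX9-mAb had a plus-strand peak from 117647 to 118417 and DHX9-Rb one from 117579 to 118386. They were 771 and 808 nt wide, near the widest peaks of their lists, 810 and 897 nt.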

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

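The tests of windows and chromosomes, of held-out peaks and of a ceiling on covered sequence were chosen after the result had been seen.

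In 6 windows the 2 antibodies differed in the part of their list, always with more weight in the DHX9-mAb list (0.937 DHX9-mAb peaks for each DHX9-Rb peak against 0.309 elsewhere). Merging of crowded DHX9-Rb peaks into fewer, wider ones would lower their number. The DHX9-Rb peaks there were indeed wide (median 332.5 nt against 218 nt in other windows with at least 20 peaks). The DHX9-mAb peaks there were wide as well (median 254 nt against 191 nt in the whole list), so width does not single out DHX9-Rb. The values argue against merging of DHX9-Rb peaks as the whole cause. The ratio of covered nucleotides was still 2.73 times that of the other windows (95% interval from resampling windows 2.03 to 3.92). These windows were picked for their peak numbers. In 200 random splits, windows were therefore picked anew on part of the peaks, a median of 3 windows per split. On the peaks held out of the picking, the median fold for the newly picked windows was 2.69 (95% of splits within 1.76 to 3.91). The splits mostly picked fewer windows than 6 and used the same lists, so they do not check each of the 6 windows. A ceiling, where DHX9-Rb has little sequence left to cover, also raises the ratio of covered nucleotides. It predicts few DHX9-mAb peaks without a DHX9-Rb partner. Outside the 6 windows 11.9% of DHX9-mAb peaks had no partner, and 5.71% in 39 other windows that leaned to DHX9-mAb without adjustment. The share was 28.0% (Wilson 14.28 to 47.58) in the chromosome 1 window from 23618464 to 23664030. It was 33.3% (19.75 to 50.39) in 1 more window. Both intervals lay above these references, where a ceiling predicts shares below them. Yet the windows were picked for many DHX9-mAb peaks, and peaks without a partner add to that number. The 39 windows did not pass after adjustment, so they do not match this picking. The shares therefore do not exclude a ceiling there. A ceiling also stays open in the rest of the 6 windows. The share was 1.85% (0.3276 to 9.771) in the chromosome 16 window, 9.09% (3.946 to 19.58) on chromosome 19 and 8.0% (3.155 to 18.84) on the mitochondrial chromosome. It was 26.3% (11.81 to 48.79) in the other chromosome 1 window, where DHX9-mAb covered 4988 nt and DHX9-Rb 4704 nt. An untested difference between the antibodies in the RNA they recover stays open as well.

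The share of the list on a chromosome passed Fisher's exact test in 4 cases, of which those on chromosomes 17 and 19 did not hold under all alternatives. DHX9-mAb had 0.732% of its peaks on the mitochondrial chromosome against 0.25% for DHX9-Rb, 3.24% against 4.19% on chromosome 7, 9.09% against 10.4% on chromosome 17, and 14.8% against 13.4% on chromosome 19. Resampling of 100 kb windows ended the call of chromosome 19 (odds ratio 1.12, interval 0.988 to 1.26), and merging of peaks within 50 nt ended those of chromosomes 17 and 19 (exact test, adjusted p = 0.085 for both). The mitochondrial chromosome could not be resampled.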

How the results depend on the processing

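The excess of overlap over random placement kept its direction and stayed past 0.05 in all 9 alternatives run, for both lists (randomization p from 0.001 to 0.01, the smallest that 1000 and 100 placements can give). The share of DHX9-mAb peaks that were shared ran from 62.1% (reciprocal overlap of 50%) to 91.8% (peaks widened by 100 nt), and that of DHX9-Rb peaks from 19.6% to 36.7% under the same rules. The fold over placement fell from 8.6 at 100 kb to 1.73 at 2 kb for DHX9-mAb and from 8.9 to 1.42 for DHX9-Rb, and rose to 18.2 and 17.5 with reciprocal overlap of 50%. The placement windows of 10 and 2 kb, the run without chromosome 19 (87.2% and 27.9%) and all tests and alternatives for widths, windows, chromosomes and strands were chosen after seeing the data. The count of windows that differed was 6 in 50 kb windows, 7 in 200 kb windows (1 of them with the larger part in DHX9-Rb), 8 with at least 20 peaks per window and 5 with peaks within 50 nt merged. Of the 4 chromosomes that differed, 2 had an interval that excluded 1 when windows were resampled (chromosomes 7 and 17), while the mitochondrial chromosome could not be resampled. Their number fell to 2 when peaks were merged (Fisher's exact test, the mitochondrial chromosome, adjusted p = 3.47e-05, and chromosome 7, adjusted p = 0.00987). The cause was not tested. Differences in width kept their sign and side, and grew from 53 to 80 nt for DHX9-Rb and from 32 to 37 nt for DHX9-mAb with peaks merged. The share of DHX9-Rb peaks outside the mitochondrial chromosome that faced a peak of the other strand moved from 0.519% to 0.399% when 50% of the shorter peak had to overlap. The planned run on the higher-scored peaks of each list and the placement within annotated genes were not run. No paired analysis was possible because each list joins both replicates and no value belongs to 1 replicate, which also rules out leaving a replicate out. Depth is unknown, so how far the ratio of 3.16 in peak numbers reflects depth was not analysed here.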

Other observations

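Runs of same-strand peaks with gaps of at most 5 kb give a view of how far peak calls extended along single strands. With no control or RNA abundance values used, the length of a run cannot be read as the extent of DHX9 contact. DHX9-Rb peaks outside the mitochondrial chromosome formed 5722 runs, of which 2644 (46.2%) were single peaks and 493 held at least 10 peaks. These 493 runs held 43.2% of the peaks. DHX9-mAb peaks formed 2801 runs, of which 110 held at least 10 peaks and 24.0% of that list. Runs on chromosome X count in the totals of both antibodies but were left out of the rankings that follow. Among the ranked runs, the longest DHX9-Rb run lay on the plus strand of chromosome 1 from 113521850 to 113584363. It held 105 peaks over 62.51 kb, of which 41.6% was covered. Next were a plus-strand run on chromosome 5 from 138942530 to 139003019, with 83 peaks over 60.49 kb, and a minus-strand run on chromosome 1 from 21453613 to 21502637, with 88 peaks over 49.02 kb. Of the ranked DHX9-mAb runs, the one with the most peaks lay on the minus strand of chromosome 19. It ran from 39437884 to 39465892, with 46 peaks over 28.01 kb. On the plus strand of chromosome 19, 25 DHX9-mAb peaks covered 61.2% of the 10.53 kb from 37824734 to 37835265.

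The test in this paragraph was planned before its result was seen. Of the 820 DHX9-mAb peaks without a DHX9-Rb peak, 730 (89.0%) lay in a 100 kb window that held a DHX9-Rb peak. On the same strand, 63.5% (Wilson 60.2 to 66.8) lay within 1000 nt of a DHX9-Rb peak, against a median of 13.7% and a highest value of 17.3% in 1000 random placements. Within 100 nt the share was 21.3%. Many of these peaks may therefore be near misses beside DHX9-Rb sites, found or lost at a region's edge or at the caller's threshold. The same closeness would follow if both antibodies recovered different sites of the same transcripts, and the lists hold no score to tell these apart. A further 178 of the 820 peaks (21.7%) lay over 10 kb from any same-strand DHX9-Rb peak.

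The count of facing peaks in dense windows was chosen after the result had been seen. Of the 10 windows outside the mitochondrial chromosome with the most DHX9-Rb peaks, 1 held any facing peaks, 31 among the 876 peaks of these windows. Leakage of reads to the wrong strand follows read depth, which the lists do not give. Leakage, transcription of both strands and reads mapped to inverted copies of a sequence were not tested here and stay open.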
